A study of Mus musculus with 8 samples.

How the data were processed

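RNA from FT1CL cells, a mouse acute myeloid leukemia line, was sequenced in 8 libraries: 4 of Cop1 wild-type cells and 4 of Cop1 knockout cells. Per the labels' protocols, total RNA was purified on columns, 2 µg entered each strand-specific library, and the knockout was made by treating cells with 4-hydroxytamoxifen, while the wild-type cells were untreated. The treatment and the genotype therefore changed together in every library. The labels do not say whether the 4 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

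Per the submitters' processing notes, Trimmomatic 0.39 and kallisto were used with genome build mm10; the aligner, the annotation release and any filter on junctions are not given in the sources used here. Per the file header, rows carry AltAnalyze junction identifiers, each an Ensembl gene with the pair of numbered exon blocks that the junction joins. The deposited values are a normalised signal per junction for 134051 junctions of 13378 genes. Tested on the values themselves, each was the junction's read count plus 1, scaled by the library's total of junction reads and a length of 60 nt, with 0 reads shown as 1 floor value of 0.854 shared by the 8 libraries. Turning this around gave whole reads for 100% of the values above the floor in each library, within 0.001 of a read. The recovered totals ran from 17333302 to 22469109 junction reads per library, and matched the totals that the step between values implies.

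Recovered junction reads were summed over the junctions of each gene and scaled by the library's total to junction reads per 1000000 (RPM). A fragment that spans several junctions counts at each of them, and genes without introns, Cebpa among them, were not analysed here. Symbols were assigned to 13247 of the 13378 genes from a table of Ensembl identifiers. Coordinates are from Gencode release M21 on build mm10 and were used for genes and for the exons of transcript Cop1-201, since the blocks in the table carry no coordinates.

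The design fixed before the data were examined foresaw kallisto counts or TPM. As the table holds neither, the branch for normalised values was used: limma 3.58.1 on log2(RPM + 1) with trend and robust moderation, for genes with a mean of at least 1 RPM, with Benjamini-Hochberg adjustment over the 11003 genes tested and a threshold of 0.05. Fold changes are on that log2 scale, knockout minus wild type, and understate changes of genes near 1 RPM. Gene lists (32 lists, 696 genes) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, for the 28 lists with at least 5 tested members. Where a list is described, counts are over all genes tested unless stated to be adjusted over the list alone. Library measures and single junctions of Cop1 were compared by exact permutation tests, two-sided, 4 against 4, whose smallest p is 0.0286. All adjusted p-values without another name come from limma.

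Genes were named by a rule fixed before the data were examined. Cop1, Trib1, Trib2 and Cebpa were always named, followed by the 12 largest rises and 12 largest falls among genes past the threshold, with no overlap between the groups and at least 10 RPM in the higher group. Symbols made of Gm and digits or ending in Rik, and identifiers without a symbol, were only counted (42 genes met the other conditions). From each list, up to 4 members with the smallest adjusted p joined these named genes, or up to 2 with the highest mean where none passed. Counts over named genes cover all of them. The text shows only some of the list members so selected, without a stated rule for that choice, and a few other members beside them.

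The replicate numbers of the labels paired the libraries. Deviations from the group means correlated at 0.32, 0.29, 0.36 and 0.55 between libraries numbered 1, 2, 3 and 4, above every correlation between different numbers (highest 0.15). The reported test has no term for the number, as fixed in advance, and a fit with the number as a block was run beside it. No libraries were duplicates: chi-square per degree of freedom between libraries of a group was at least 30.8.

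Some junction values were far too low for their gene. A value was called dropped when it held at most 6 reads while the gene's other junctions predicted at least 100, after scaling each library to a common total. This held for 30717 values, 6.70% of those of the 57273 junctions that reached 100 scaled reads in some library, and touched 9705 junctions of 3107 genes. The main sums keep these values as deposited. Sums without the affected junctions were made as an alternative chosen after seeing the data. Summed and mean levels of gene lists per library use those sums.

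Use of junctions within a gene was tested with limma's diffSplice on log2(RPM + 0.05) for 36034 junctions of 4703 genes, with a mean of at least 100 scaled reads and no dropped value. Reads of near-identical paralogs (Stfa2, Stfa2l1 and Stfa3, Hba-a1 and Hba-a2, and relatives of Lyz2, Ly6c2, Gzmb and Mcpt8) may be assigned to the wrong copy. Other alternatives were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, other scalings, filters and pseudocounts, camera with an estimated correlation, fry, and leaving out each library. R was version 4.3.3.

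The steps were tested on simulated data. With counts simulated for 4 knockout and 4 wild-type libraries and 200 genes changed, limma (10948 genes) found 0 of 50 genes changed 1.5-fold, 11 of 50 changed 2-fold, 46 of 50 changed 4-fold and 44 of 50 changed 8-fold, with 7 unchanged genes called. In simulated junction counts (36034 junctions) the usage test found 92 of 100 junctions changed 2-fold and 100 of 100 changed 4-fold, with 13 calls in genes that were not changed. Those counts had the same fixed dispersion (spread beyond the sampling of reads) at every junction and no other difference between groups. They therefore do not set the share of changed junctions that could be found in the data. The search for dropped values found 995 of 1000 values lowered on purpose, and newly marked 121 values that were not lowered.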

Results

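FT1CL cells were compared with and without Cop1, the gene of a ubiquitin ligase that works with Tribbles proteins to mark C/EBPα for degradation. The line is a mouse acute myeloid leukemia made from bone marrow transduced with a retrovirus carrying Trib1, and it grew in medium with interleukin-3. Cop1 can be deleted in these cells by a Cre recombinase that 4-hydroxytamoxifen activates, and only the knockout cells received it. The 4 wild-type libraries held 17811247 to 20981993 junction reads and the 4 knockout libraries 17333302 to 22469109. Neither depth (exact permutation p = 0.60) nor the share of junction values far below those of the rest of their gene (6.76 ± 0.452% and 6.65 ± 0.254%, SD, n = 4, exact permutation p = 0.66) differed between groups beyond the spread. The number of genes with at least 10 reads was 11314 ± 82.9 in wild type and 11491 ± 97.0 in knockout (SD, n = 4, exact permutation p = 0.057).

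Knockout libraries 1 to 3 lay apart from wild type, and both libraries numbered 4 lay apart from the rest of their group. Correlations across genes of log2 values were 0.969 to 0.981 among wild-type libraries 1 to 3 and 0.970 to 0.975 among knockout libraries 1 to 3. Knockout library 4 correlated at 0.934 to 0.941 with the other knockout libraries and at 0.935 to 0.943 with the wild-type libraries. On the first principal component (49.4% of the variance) wild type ran from -57.0 to -18.8, knockout libraries 1 to 3 from 40.6 to 49.4, and knockout library 4 was at -1.52. On the second (19.2%) the libraries numbered 4 were at -24.4 and -48.8 and the others between -2.28 and 26.6.

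Cop1 reads were lower in all 4 knockout libraries, most of all at the junctions on either side of exon block 3. Summed over 19 junctions, Cop1 (ENSMUSG00000040782, chromosome 1, 159232320 to 159347640) gave 162 ± 2.92 RPM in wild type and 73.7 ± 6.47 RPM in knockout (SD, n = 4), a log2 fold change of -1.13 (SE 0.08, adjusted p = 4.91e-04). The 2 junctions that join block 3 to blocks 2 and 4 averaged 5.11 ± 0.285 RPM in wild type and 1.11 ± 0.247 RPM in knockout, 21.8% of the wild-type level. The other 17 junctions averaged 8.95 ± 0.171 and 4.20 ± 0.369 RPM, or 47.0%. Relative to the other junctions, those beside block 3 had a ratio of 0.571 ± 0.0344 in wild type and 0.265 ± 0.0558 in knockout (SD, n = 4, exact permutation p = 0.0286, the smallest possible). The ratio was not in the design fixed in advance, and these junctions had the lowest knockout share of the 19. Its p is therefore a description only. In transcript Cop1-201, whose 20 exons match the blocks in number only, exon 3 spans 159244589 to 159244686.

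**Figure D1:**
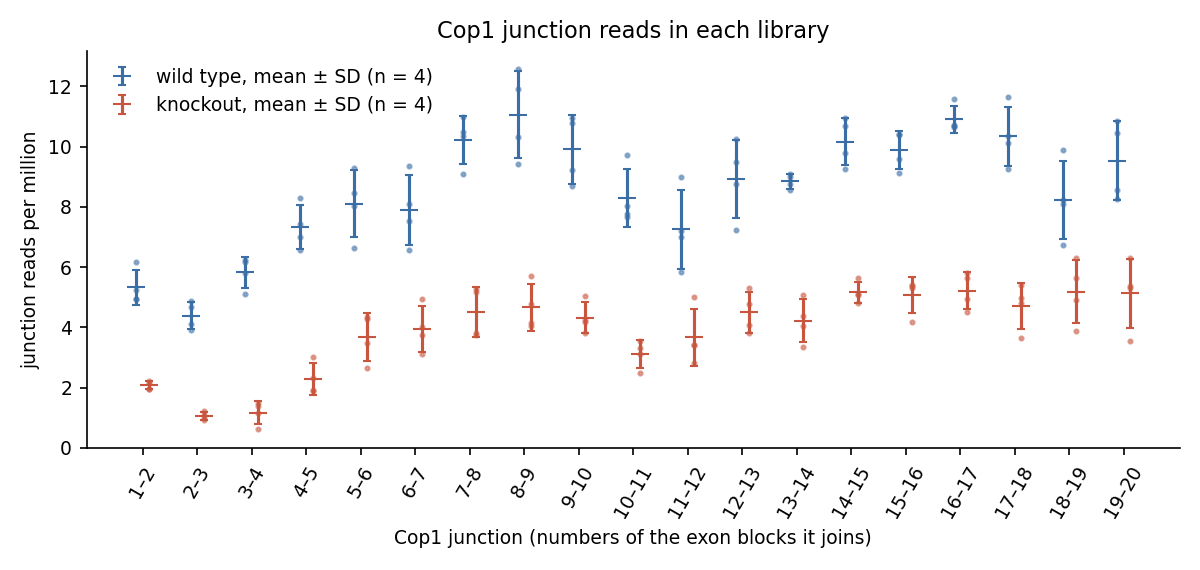
RPM (y axis) for each of the 19 Cop1 junctions (x axis, the pair of exon blocks joined), with points for single libraries and bars for mean ± SD (n = 4). Knockout libraries lie below wild-type libraries at each junction, and at 24.2% of the wild-type mean where block 2 joins block 3.

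The other Tribbles genes gave no call in limma without pairing. Trib1 (chromosome 15, 59648350 to 59657099), the gene carried by the retrovirus, had 446 ± 221 RPM in wild type and 941 ± 473 RPM in knockout (SD, n = 4), a log2 fold change of 1.06 (SE 0.49, adjusted p = 0.16). With the replicate number as a block it passed, at adjusted p = 0.021 (6.85e-04 to 0.423 over all alternatives). One of its 2 junctions held 1 read in wild-type library 4 where the other held 6410. Reads of the introduced copy and of the cell's own gene would fall on the same junctions. Trib2 was read only in the libraries numbered 4 (27 reads in wild type and 10 in knockout) and was not tested. In the list of the COP1 ligase and Tribbles, 2 of 9 tested members were lower, Cop1 and Cul4b (5 lower when adjusted over the list alone, 1 higher and 2 lower with the replicate block). The list did not pass (median -0.26, camera adjusted p = 0.29). Cul4b, a scaffold of the ligase, had -0.33 (SE 0.10, adjusted p = 0.046), a call that ended without any 1 of 7 libraries, all but knockout library 4 (adjusted p 0.066 to 0.113), and under TMM scaling (0.089).

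Knockout cells had far more RNA of neutrophil granule and secreted proteins and less RNA of genes for DNA replication and ribosome assembly. The largest rises on the log2(RPM + 1) scale were in Ngp (neutrophilic granule protein; 2.53 ± 3.13 to 1114 ± 1106 RPM, SD, n = 4, log2 fold change 7.73, SE 1.07, adjusted p = 0.0039) and Ltf (lactoferrin; 5.99 ± 2.27 to 2028 ± 1916 RPM, 7.44, SE 0.93, adjusted p = 0.0027). The next were Stfa2 (6.61), Lipg (6.25), Stfa2l1 (6.23), Stfa3 (6.20), Mmp8 (6.19), Lcn2 (5.75), Myo18b (5.58), Alox15 (5.33), Mmp13 (5.00) and Lyz2 (4.86), with adjusted p of 7.22e-04 to 0.0071. Among these are collagenases (Mmp8, Mmp13), the iron-binding lipocalin 2 (Lcn2), lysozyme (Lyz2) and 3 stefin A genes, whose near-identical copies may share reads. Knockout library 4 was below the other knockout libraries for each of the 12 except Lipg. Mmp8, for example, had 98.1 RPM there and 1328 to 1614 RPM in the others.

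The largest falls on that scale after Rps9 were in Pkd2l1 (a cation channel; -4.51), Cdh23 (a cadherin; -3.44), Timp3 (a metalloproteinase inhibitor; -3.18), Plb1 (-2.91), Neb (nebulin; -2.87), Tgm2 (transglutaminase 2; -2.87), Lck (a lymphocyte kinase; -2.87), Grtp1 (-2.86), Fgf3 (-2.83), Gbp4 (-2.72) and Hba-a1 (alpha globin; -2.61). Cdh23 went from 102 ± 13.8 to 8.86 ± 3.23 RPM (SD, n = 4, SE 0.23, adjusted p = 4.44e-04), and Neb from 282 ± 87.1 to 37.5 ± 10.4 RPM (SE 0.26, adjusted p = 0.0010, and 0.25 from its most-read junction alone). Plb1 lost its call in 15 of 27 alternatives. Among them were those without wild-type library 1, 3 or 4 or knockout library 1, 2 or 3 (adjusted p 0.055 to 0.108). It had -1.46 (adjusted p = 0.196) from its most-read junction alone. Gbp4 was read most in wild-type library 4 (72.1 RPM, and 6.30 to 8.72 RPM in the other wild-type libraries) and had -1.74 without both libraries numbered 4. It lost its call without wild-type library 2 or knockout library 1 or 3 (0.053 to 0.072) or with a pseudocount of 5 (0.071). Rps9, a ribosomal protein gene, had the largest listed fall (-4.63, adjusted p = 8.24e-08), which came from 1 junction with 12283 to 14700 reads in wild type and 1 to 3 in knockout. With such junctions left out Rps9 had a log2 fold change of 0.70 (adjusted p = 0.021), so its direction turned.

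In all, 2264 of 11003 genes tested (20.6%) passed the threshold, 934 higher and 1330 lower in knockout. At least 2-fold changes numbered 465 higher and 161 lower. The groups did not overlap for 2767 genes (25.1%), where chance gives 2.86%. With TMM scaling, 1092 genes were higher and 972 lower, so the share of higher genes moved from 41.3% to 52.9%. Without junctions that had a dropped value, 3007 genes passed (1154 higher, 1853 lower), 2208 of them also among the 2264 and in the same direction. With the replicate block 3084 genes passed (1357 higher, 1727 lower), and 4146 with the block and those junctions left out. DESeq2 gave 1668 higher and 1387 lower. Without both libraries numbered 4, 2734 genes passed (1196 higher, 1538 lower). The count fell to 1485, 1271 or 1509 without wild-type library 1, 2 or 4, and to 1435, 1371 or 1215 without knockout library 1, 2 or 3.

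Genes of granulocyte maturation rose together. In the list of secondary and late neutrophil genes, 13 of 24 tested members rose and none fell (17 rose when adjusted over the list alone, 18 with the replicate block and 22 without both libraries numbered 4), with a median log2 fold change of 2.13 (camera adjusted p = 2.72e-10, and adjusted p = 0.454 with an estimated correlation). Ltf, Ngp and Lcn2 are among them. With junctions that had a dropped value left out, the summed level of this list was 9968, 17542 and 11017 RPM in knockout libraries 1, 2 and 3, and 2154 RPM in knockout library 4, against 778 to 1848 RPM in wild type. Of 14 C/EBP factors and granulocyte regulators, 7 rose and none fell (7 over the list alone, median 1.06, adjusted p = 0.0018, and adjusted p = 0.454 with an estimated correlation). Csf2rb, the shared receptor chain for interleukin-3 and GM-CSF, went from 1171 ± 182 to 2495 ± 241 RPM (SD, n = 4, log2 fold change 1.10, SE 0.13, adjusted p = 0.0023), and Csf2ra rose by 1.06 (SE 0.20, adjusted p = 0.0095). In the primary granule list 4 of 12 rose and none fell (5 over the list alone, 5 higher and 1 lower with the replicate block, 4 and 1 without both libraries numbered 4, median 1.06, adjusted p = 0.0083, and adjusted p = 0.454 with an estimated correlation). The protease inhibitor Serpinb1a had 2.45 (SE 0.24) and cathepsin G (Ctsg) went from 523 ± 409 to 1882 ± 377 RPM (SD, n = 4). Igsf6 (3.09) and Ms4a3 (1.87) also rose, but each lost its call without any 1 of 6 libraries (adjusted p 0.066 to 0.089). Mpo (0.79, adjusted p = 0.47), Elane (1.34, 0.37) and Prtn3 (-0.06, 0.97) gave no call. A positive fold change was seen in 8 of the 12 primary granule genes. Among monocyte and macrophage genes, 4 of 14 rose and none fell (4 over the list alone, 7 higher and 1 lower with the replicate block, 6 higher without both libraries numbered 4, median 0.72, adjusted p = 0.0084, and adjusted p = 0.536 with an estimated correlation). The lipopolysaccharide receptor Cd14 went from 0.467 ± 0.692 to 12.7 ± 7.85 RPM and the oxidase subunit Cybb from 0.117 ± 0.110 to 8.35 ± 6.42 RPM (SD, n = 4). Of the 14 tested monocyte and macrophage genes, 10 had a positive fold change. Csf1r (-0.28), Irf8 (-0.54), Ccr2 (-0.16) and F13a1 (-0.47) went the other way without a call (adjusted p 0.58 to 0.84). The monocyte list's adjusted p was 0.066 without wild-type library 4 and 0.228 in edgeR with a minimum of 10 RPM.

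**Figure D2:**
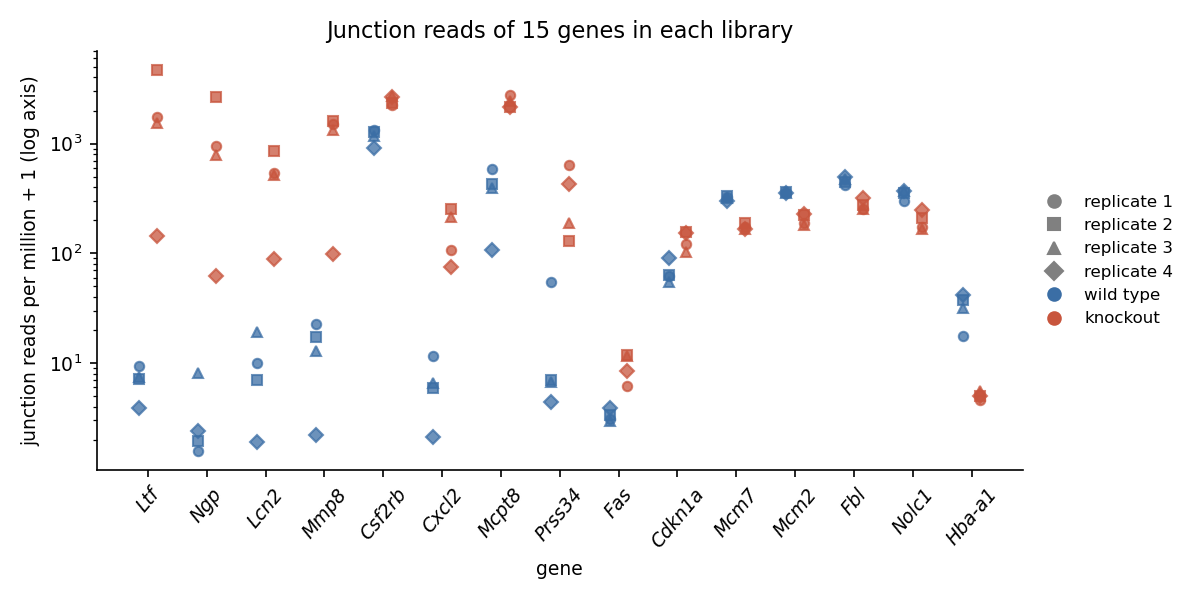
RPM plus 1 (y axis, log scale) of 15 genes (x axis) in each of the 8 libraries, blue for wild type and red for knockout, with a marker shape per replicate number. Ltf, Ngp, Lcn2 and Mmp8 are higher in each knockout library than in each wild-type library and lower in knockout library 4 than in the other knockout libraries, whereas Mcm7, Mcm2, Fbl and Nolc1 are lower in knockout with little spread.

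Genes of DNA replication and of ribosome assembly fell together. In the S phase list 17 of 34 members fell and none rose (18 fell over the list alone, 24 with junctions that had a dropped value left out, median -0.56, camera adjusted p = 4.62e-08, and adjusted p = 0.454 with an estimated correlation). Mcm7, a subunit of the replicative helicase, went from 318 ± 13.8 to 172 ± 9.64 RPM (SD, n = 4, log2 fold change -0.88, SE 0.07, adjusted p = 7.08e-04). Mcm2 (-0.80), Mcm4 (-0.81) and the polymerase subunit Pola1 (-0.70) were similar, with adjusted p of 0.0019 to 0.0023. In the G2 and mitosis list 11 of 34 fell and none rose (13 over the list alone, 17 with such junctions left out, 8 without both libraries numbered 4, median -0.27, adjusted p = 6.26e-04, and adjusted p = 0.454 with an estimated correlation), among them the checkpoint kinase Bub1b (-0.57, SE 0.09) and topoisomerase Top2a (-0.50, SE 0.10). In the list of ribosome biogenesis and MYC, 18 of 29 fell and none rose (18 over the list alone, 26 with such junctions left out, median -0.62, adjusted p = 3.84e-06, and adjusted p = 0.454 with an estimated correlation). Fibrillarin (Fbl) went from 459 ± 34.8 to 274 ± 31.5 RPM (SD, n = 4, -0.74, SE 0.10, adjusted p = 0.0032), Nolc1 by -0.81 (SE 0.14), Wdr43 by -0.69 (SE 0.09) and nucleolin (Ncl) by -0.58 (SE 0.09).

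**Figure D3:**
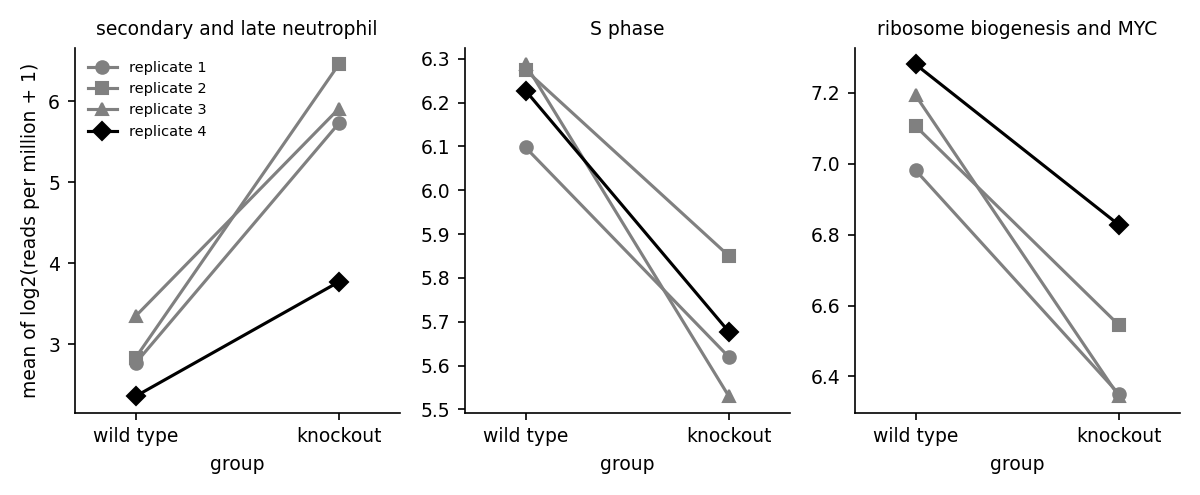
Mean of log2(RPM + 1) over the members of 3 lists (y axis) in wild type and knockout (x axis), with junctions that had a dropped value left out and a line joining the libraries of each replicate number (number 4 in black). The neutrophil list differs by 1.41 in number 4 and by 2.56 to 3.62 in the others, while the S phase list falls in each number.

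Lists of inflammation, interferon, cytokine, p53 and unfolded protein genes were higher too. In the inflammatory and NF-kB list 9 of 21 rose and 1 fell (11 and 2 over the list alone, median 1.14, camera adjusted p = 1.56e-05, and adjusted p = 0.454 with an estimated correlation). The chemokine Cxcl2 went from 5.52 ± 3.85 to 161 ± 84.1 RPM (SD, n = 4, log2 fold change 4.70, SE 0.56, adjusted p = 0.0023), Ptgs2 (cyclooxygenase 2) rose by 2.94 (SE 0.43) and Ccl3 by 1.82 (SE 0.38). Of 23 interferon response genes 5 rose and none fell (5 over the list alone, median 0.50, adjusted p = 1.91e-04, and adjusted p = 0.454 with an estimated correlation), including the nucleic acid sensor Zbp1 (1.76, SE 0.20) and Oas3 (1.57, SE 0.31, adjusted p = 0.011, and 0.063 from its most-read junction alone). Cytokine and STAT output had 7 higher and 2 lower of 17 (8 and 2 over the list alone, median 0.51, adjusted p = 0.0075, and adjusted p = 0.454 with an estimated correlation), with the feedback inhibitor Cish at 0.81 (SE 0.14), Il3ra at 0.87 (SE 0.17) and the kinase Pim2 at -1.45 (SE 0.21). Of 26 p53 targets 4 rose and 1 fell (4 and 1 over the list alone, 10 and 1 with the replicate block, 7 and 1 without both libraries numbered 4, median 0.42, adjusted p = 6.26e-04, and adjusted p = 0.454 with an estimated correlation). The death receptor Fas (1.47, SE 0.24) and the cell cycle inhibitor Cdkn1a (0.97, SE 0.19) rose. Sesn1 (-0.55) fell, a call that ended without any 1 of 7 libraries, all but knockout library 4 (adjusted p 0.052 to 0.078). Of 21 unfolded protein response genes 3 rose and none fell (5 over the list alone, 5 with the replicate block, 7 with junctions that had a dropped value left out, median 0.31, adjusted p = 2.39e-04, and adjusted p = 0.454 with an estimated correlation), including Edem1 (1.21, SE 0.16) and Pdia4 (0.91, SE 0.14).

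The list of JUN and ETS substrates and MAPK output had 3 of 21 higher and none lower (3 over the list alone, 5 higher with the replicate block, median 0.45, camera adjusted p = 0.031, and adjusted p = 0.454 with an estimated correlation), with the AP-1 members Fosl2 (19.5 ± 2.54 to 39.8 ± 3.21 RPM, SD, n = 4) and Fosl1 (1.40, SE 0.21). Without both libraries numbered 4 it had 4 higher and 4 lower, and without junctions that had a dropped value 4 higher and 1 lower. This list lost its call in 19 of 28 alternatives. Among them were those without wild-type library 3 or 4 or knockout library 4 (adjusted p 0.080, 0.103 and 0.132), without both libraries numbered 4 (0.244) and under TMM scaling (0.063). Heat shock and handling stress had 2 of 9 lower (2 over the list alone, 3 without both libraries numbered 4, median -0.25, adjusted p = 0.12). Without junctions that had a dropped value 5 were lower (camera adjusted p = 0.037, and adjusted p = 0.484 with an estimated correlation). The chaperone Hsph1 had -0.69 (SE 0.15, adjusted p = 0.016, and 0.060 from its most-read junction alone). The apoptosis list had 1 of 20 higher, Mcl1, and did not pass (0 over the list alone, median 0.09, adjusted p = 0.48). It had 5 higher and 3 lower with the replicate block, 3 and 1 without both libraries numbered 4, and 1 and 3 without junctions that had a dropped value. Mcl1, an antagonist of apoptosis, had 0.51 (SE 0.14), a call that ended without wild-type library 2, 3 or 4 or knockout library 1, 2 or 3 (adjusted p 0.058 to 0.090).

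Lipid and amino acid genes went both ways. Fatty acid synthesis had 7 of 18 lower and 2 higher (9 and 2 over the list alone, median -0.39, camera adjusted p = 0.063). The desaturases Fads2 (671 ± 32.1 to 350 ± 88.3 RPM, SD, n = 4; log2 fold change -0.97, SE 0.15, adjusted p = 0.0054) and Scd2 (806 ± 138 to 404 ± 89.0 RPM) were lower, and Dgat1, which makes triglycerides, was higher (17.9 ± 4.89 to 84.0 ± 24.7 RPM, 2.16, SE 0.27, adjusted p = 0.0026). Without both libraries numbered 4 the adjusted p of this list was 0.018, and with TMM scaling it was 0.042. With all libraries and no TMM scaling it had adjusted p = 0.454 with an estimated correlation. Cholesterol synthesis had 1 higher and 1 lower of 26 (1 and 1 over the list alone, median -0.04, adjusted p = 0.99), the higher one being Cyp51 (0.80, SE 0.14) and the lower one Acat2 (-0.71). Acat2 lost its call without wild-type library 2 or 3 or knockout library 1 or 3 (adjusted p 0.0503 to 0.0583). Without both libraries numbered 4, 1 member of this list was higher and 4 lower, and without junctions that had a dropped value 1 and 2. The median of this list was negative and camera gave it an upward direction. Amino acid stress had 3 higher and 6 lower of 29 (3 and 8 over the list alone, median -0.06, adjusted p = 0.999). The cystine transporter Slc7a11 (2.86, SE 0.42) and Atf3 (2.14, SE 0.44) were higher, and Shmt2 (-0.95, SE 0.17) and Phgdh (-0.74, SE 0.15), enzymes of serine and one-carbon metabolism, were lower. Glycolysis and hypoxia had 1 of 27 higher (0 over the list alone, median 0.35, adjusted p = 0.0075, and adjusted p = 0.470 with an estimated correlation). Its adjusted p was 0.105 without knockout library 4. Without both libraries numbered 4, 2 were higher and 1 lower, and its adjusted p was 0.225. With junctions that had a dropped value left out, 7 were higher and 1 lower (camera adjusted p = 3.82e-04, and adjusted p = 0.461 with an estimated correlation). The higher gene, the lactate exporter Slc16a3 (1.04, SE 0.29, adjusted p = 0.036), had adjusted p = 0.052 with the replicate block and lost its call without 6 of the libraries, all but wild-type libraries 1 and 4 (adjusted p 0.056 to 0.093). Oxidative phosphorylation had 5 of 35 lower (0 over the list alone, 1 higher and 6 lower with the replicate block, 1 and 8 without junctions that had a dropped value, median -0.10, adjusted p = 0.34), with Sdha at -0.40 (SE 0.09, adjusted p = 0.017, and 0.052 without wild-type library 2). Estrogen receptor targets had none of 6 past the threshold (0 over the list alone, median -0.19, adjusted p = 0.80). With the replicate block 1 was higher, without both libraries numbered 4 it was 2, and without junctions that had a dropped value 2 were higher and 1 lower. Of these, Igfbp4 had -0.32 (adjusted p = 0.54), and -1.26 (adjusted p = 0.0027) without junctions that had a dropped value.

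Markers of other blood cells changed too. With junctions that had a dropped value left out, the mast cell and basophil list summed to 17109 ± 1166 RPM in wild type and 20389.5 ± 3074 RPM in knockout (SD, n = 4). Most of this sum in each library was the mast cell protease gene Cpa3 (10079 to 15363 RPM), so it does not describe the list as a whole. In this list 6 of 16 members rose with none lower (8 higher and 1 lower over the list alone, 7 and 2 with the replicate block, 7 and 2 without both libraries numbered 4, median 0.72, camera adjusted p = 6.26e-04, and adjusted p = 0.454 with an estimated correlation). The basophil proteases Mcpt8 (377 ± 198 to 2381 ± 304 RPM, SD, n = 4; log2 fold change 2.89, SE 0.47, adjusted p = 0.0061) and Prss34 (4.79, SE 0.82, adjusted p = 0.0075) and the mast cell chymase Cma1 (1.63, SE 0.21) rose. Of 4 tested eosinophil genes 1 rose, Alox15 (2 over the list alone, 2 higher and 1 lower with the replicate block or without both libraries numbered 4). The erythroid list had 3 of 9 lower (5 over the list alone, 6 with the replicate block, 7 without both libraries numbered 4, 2 of 8 without junctions that had a dropped value, median -0.65, adjusted p = 0.015, and adjusted p = 0.454 with an estimated correlation), with the near-identical globins Hba-a1 (-2.61) and Hba-a2 (-2.51). Its mean log2 level was 5.09 and 3.94 in wild-type and knockout library 4, against 3.44 to 3.57 and 2.46 to 2.67 in the others, with junctions that had a dropped value left out.

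Of 7 megakaryocyte genes 2 rose, Vwf (1.71, SE 0.29) and F2rl2 (1.16, SE 0.18), and the list did not pass (2 over the list alone, median -0.17, camera adjusted p = 0.62). The lymphoid list had 1 higher and 2 lower of 7 (1 and 2 over the list alone, 1 and 4 with the replicate block, median -0.71, adjusted p = 0.31), the lower ones being Lck and granzyme B (Gzmb). Gzmb went from 4358 ± 1641 to 2034 ± 297 RPM (SD, n = 4, log2 fold change -1.02, SE 0.27, adjusted p = 0.032), a call that ended without wild-type library 1, 2 or 4 or knockout library 1, 2 or 3 (adjusted p 0.054 to 0.087) or without both libraries numbered 4 (0.056). Dendritic cell genes had 1 of 10 higher, Bst2 (0.39, SE 0.07), which also belongs to the interferon list (1 over the list alone, 1 higher and 3 lower with the replicate block, median -0.20, adjusted p = 0.99). Among 4 stroma and endothelium genes 1 was lower, Pdgfrb (-1.91, SE 0.30; 1 over the list alone, 1 higher and 1 lower with the replicate block or without both libraries numbered 4). The stem and progenitor list had 2 higher and 2 lower of 17 (2 and 2 over the list alone, 2 and 4 with the replicate block or without both libraries numbered 4, median -0.29, adjusted p = 0.98). Cd93 (1.31, SE 0.18) and Fli1 (0.46, SE 0.08) were higher. Myc (-0.69) and Cd34 (-1.56) were lower. Myc lost its call without wild-type library 1, 2 or 3 or knockout library 3 (adjusted p 0.053 to 0.067), and Cd34 without wild-type library 2, 3 or 4 or knockout library 1 or 2 (0.056 to 0.082). With TMM scaling Myc had 0.051, and in edgeR Cd34 had 0.052. Of the replication-dependent histones only Hist1h2bc was read (0.53, adjusted p = 0.060, and 0.038 with the replicate block), and no gene of the mitochondrial genome was in the analysis.

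**Figure D4:**
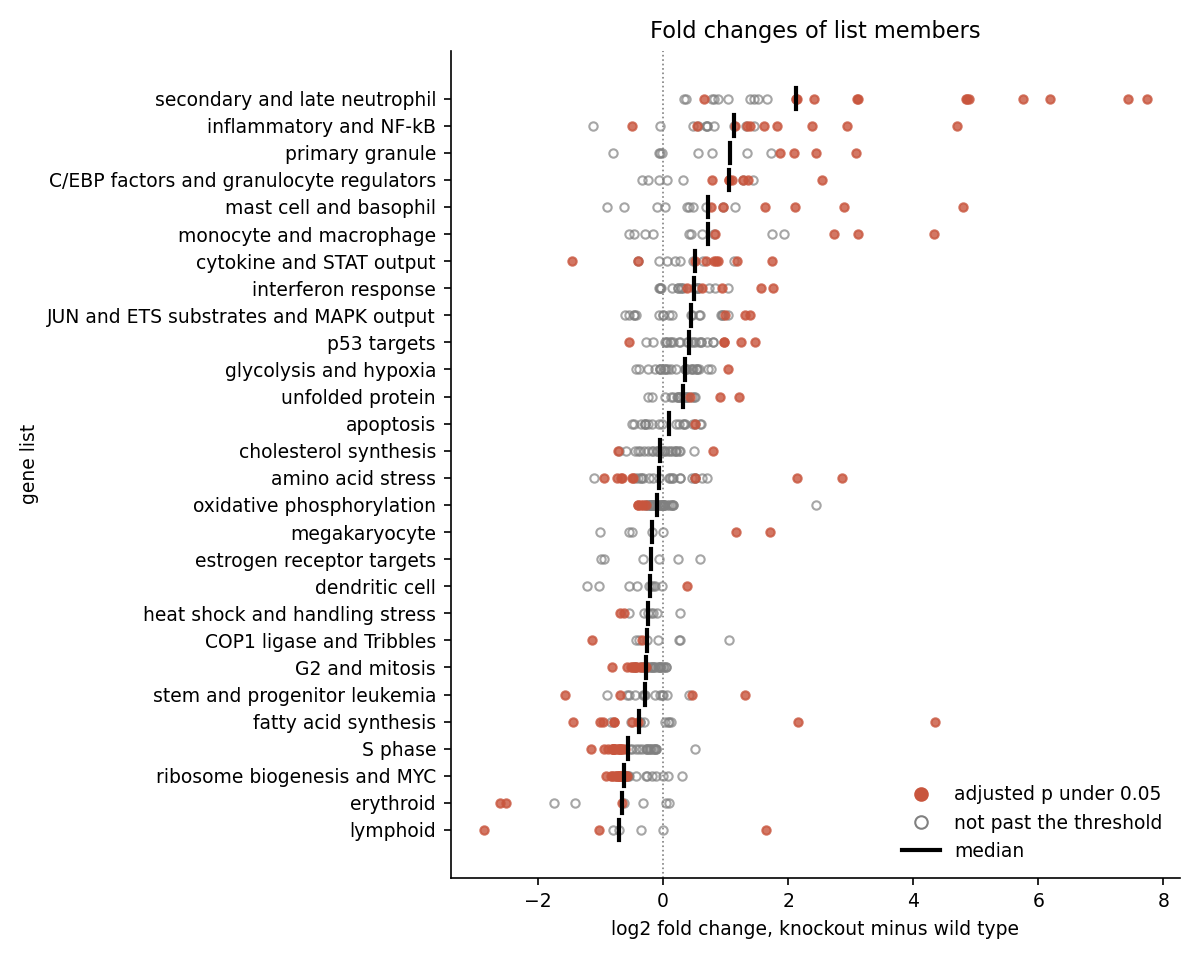
Log2 fold change, knockout minus wild type (x axis), of each tested member of the 28 lists with at least 5 tested members (y axis), filled where the adjusted p was under 0.05, with a bar at the list's median. Medians run from -0.71 in the lymphoid list to 2.13 in the secondary and late neutrophil list.

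The number of genes whose use of junctions changed depended on which junctions were tested. Of 4703 genes tested, 7 had a junction whose share of the gene differed (10 junctions; limma's diffSplice, adjusted p under 0.05), 17 genes with the replicate block, and 14 without knockout library 4. Of these junctions 4 differed at least 2-fold from their gene, and they are named here after their values were seen. Cndp2, a dipeptidase gene, had 2 of them: the junction into block 3 went from 1.83 ± 0.764 to 15.1 ± 2.65 RPM (SD, n = 4, 1.89 on the log2 scale relative to the gene, adjusted p = 1.14e-11), and the junction before it moved by -1.17. The others were in Dgkz (1.26, adjusted p = 9.60e-06) and Srebf1 (-1.05, adjusted p = 4.35e-05), the gene of a transcription factor of lipid synthesis. Junctions under 100 scaled reads were not screened for dropped values. With a minimum of 50 the count was 85 genes, and with one of 200 it was 1. With dropped values kept in it was 166 genes (193 junctions). Junctions with a dropped value were left out beforehand, among them 51 dropped in all libraries of one group only. A junction with almost no reads in one group could therefore not be called. The junctions beside Cop1 block 3 were below the minimum of 100.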

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

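The 3 tests on knockout library 4 were chosen only after the result was seen, and the test of a shared state replaced an earlier one after that one's value was seen. A library stood apart from the other 3 of its group, by more than 0.829 of the group's range, in 22 of 298 groups of values, where chance gives 14.9 (about 1 in 20). Wild-type library 4 was the one apart in 9 of them and knockout library 4 in 8.

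In wild-type library 4 the gap to the nearest other library, as a share of the range, was 1 for Trib2, 0.880 for Alox15, 0.875 for Gbp4, 0.922 for Ptgs2, 0.834 for Scd2 and 0.852 for Atf3. For lists in that library it was 0.888 for stem and progenitor genes, 0.909 for cholesterol synthesis and 0.919 for erythroid genes. In knockout library 4 it was 1 for Trib2, 0.930 for Mmp8, 0.866 for Alox15, 0.908 for Ly6c2, 0.870 for Myc and 0.935 for Fads2, and for lists 0.840 for eosinophil and 0.859 for erythroid genes. Elsewhere it was 0.870 for Lyz2 and 0.964 for Fgf3 in wild-type library 3, 0.860 for Ccna2 in wild-type library 1, 0.872 for Top2a in knockout library 1 and 0.842 for the interferon list in wild-type library 2.

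Neutrophil genes rose less in knockout library 4 than in the other knockout libraries. Less deletion of Cop1 is argued against, since the junctions beside block 3 averaged 0.801 RPM there and 1.05 to 1.37 RPM in the others, and so is less exit from the cell cycle, as the S phase list differed by -0.55 in number 4 and by -0.76 to -0.42 in the others. Over the whole neutrophil list, the earlier test of a state shared by both libraries numbered 4, the difference was 1.41 in number 4 and 2.56 to 3.62 in the others, but most members are so low in wild type that a shared fall would shrink it. Such a state cannot be told apart, since the 9 neutrophil genes with at least 10 RPM on average in wild type differed by a median of 1.84 in number 4 and 1.43 to 2.19 in the others, but by a mean of 2.07 against 2.26 to 2.72. A difference in culture or in time since treatment may remain, and was not tested.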

How the results depend on the processing

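Settings that leave out junctions with dropped values, combine them with other choices, or change the read minimum of the junction test were chosen only after the result was seen. Of 3034 alternatives over 109 named genes, 2753 kept direction and side of the threshold, 239 lost the call, 38 gained one and 4 reversed. Of 777 over 28 lists, all with camera at the preset correlation, the counts were 737, 23, 17 and 0. Cop1 kept its call in 28 of 28, with -1.18 to -1.04. Rps9 reversed to 0.70 with dropped-value junctions left out, 0.70 with the replicate block as well, 0.78 in edgeR and 0.77 with TMM scaling, because the alternative removes the junction behind its fall. Genes higher numbered 1668 in DESeq2 and 1544 in edgeR with the replicate block, and genes lower 843 in edgeR with no filter and 800 with at least 10 RPM; the cause was not tested. With dropped-value junctions left out and the replicate block, 4146 genes changed, 1703 higher and 2443 lower. Leaving out 1 library gave 1215 to 2991 changed genes, 509 to 1249 higher and 706 to 1742 lower, with fewer libraries in each fit. Gene lists past the threshold fell from 16 to 0 with an estimated correlation, to 0 with the replicate block as well, to 0 with dropped-value junctions left out and to 0 with both, so these settings ended each list call. fry, which tests a list against no change and not against other genes, passed 14 lists, not all of them among the 16. Genes with changed junction use numbered 17 with the replicate block, 85 with a minimum of 50 reads, 1 with 200, 166 with dropped values kept in, and 7 to 14 without 1 library; the cause was not tested. Among named genes the replicate block, which uses the pairing of numbers, gave Trib1 adjusted p = 0.021 and Hist1h2bc 0.038, and ended the calls of Dnajb9 (0.051) and Slc16a3 (0.052), and it changed no other call. On simulated data, with 200 genes changed and 10948 tested, 0 of 50 genes changed 1.5-fold were found. In the data 20.6% of the genes passed, a larger share, and smaller changes were called, such as Bst2 (0.39 on the log2 scale). The simulation therefore does not set the smallest change that could be called in the data.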

Other observations

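The tests on depth, sterol genes, p53 targets and splits were planned, and the tests on junction values with few reads were chosen only after the result was seen. Some genes, named after their values were seen, were read mainly in the libraries numbered 4. Pde11a had 4217 reads in wild-type and 5476 in knockout library 4, 211 and 115 in the libraries numbered 3, and 0 in the others. Hoxa9 had 1560 and 934 reads in the libraries numbered 4, 149 and 326 in those numbered 3, and 0 in the others. With junctions that had a dropped value left out, Ppia had 744 and 661 RPM in wild-type and knockout library 3. It had at most 2.61 RPM in the other libraries. What confined reads to a replicate number was not tested. Cpa3, a mast cell protease gene, had 10079 to 15363 RPM in the 8 libraries, with junctions that had a dropped value left out.

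Chance is argued against as the source of the 2264 changed genes, but so few splits, with libraries paired by number, cannot exclude it. Of 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many. The highest of the others gave 7, and the 7 others that part all 4 pairs gave at most 1. The other splits mix the groups, which widens the spread within each side. Depth is argued against, since 96.6% of the calls were left after thinning each library to 17333302 reads. As only knockout cells received 4-hydroxytamoxifen, the drug could act beside the deletion, and an effect on sterol metabolism cannot be told apart from none, because the cholesterol list had a median of -0.043 (resampling range -0.17 to 0.11) over members that went both ways. A response to DNA breaks by activated Cre may contribute, as the p53 targets had a median of 0.42 (0.16 to 0.61). The ranges were not in the plan, by which a median that was not positive counted against the effect on sterol metabolism. The cholesterol list met that. Both ranges resample the members of a list and not the libraries, so they do not measure the spread between libraries. With an estimated correlation the p53 list did not pass (camera adjusted p = 0.454). The loss of Cop1 itself could raise p53 targets too, and the design does not separate these causes.

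Junction values of at most 6 reads where at least 100 were predicted numbered 30717, and 2686 junctions were affected in at least 5 libraries, where independence gives 3.66. Whether too few reads caused them cannot be tested this way, since the definition already asked for at least 100 predicted reads. Their share did not fall with depth: it was 6.22% at 100 to 200 scaled reads and 7.84% at 1000 or more. Reads lost from the table would leave 0, yet 0.0293% of these values were 0 and 15392 of them held 1 read. Splicing that differs between groups is argued against as the whole cause: of 1190 junctions affected in 4 libraries, 4.29% were affected in all 4 of one group, where chance gives 2.86%. Another count standing in the place of the true one could remain, and was not tested.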
